A study of Mus musculus with 60 samples.

How the data were processed

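RNA from a highly differentiation-inducible mouse erythroleukemia cell line was compared after and before treatment on 2-colour cDNA arrays. Cells were treated with 1.5% DMSO (dimethyl sulfoxide), 5 mM HMBA (hexamethylene bisacetamide) or 30 nM TSA (trichostatin A, a histone deacetylase inhibitor) for 1, 6, 12, 24 or 36 h, which gave 15 conditions with 4 arrays each, 60 arrays in all. One label of the DMSO samples prints the dose without its decimal point; the titles and the series description give 1.5%. Per the labels, the 4 arrays of a condition are technical replicates, 2 of them with the dyes swapped. The after-treatment RNA was in Cy5 on replicates 1 and 2 and in Cy3 on replicates 3 and 4. No time-matched untreated culture was labelled, and whether the before-treatment RNA was 1 extract or several is not given in the sources used here.

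Each array consisted of 2 slides, and its deposited files list a clone identifier with 2 spot intensities per slide, before and after treatment. These intensities are on a linear scale, per the file headers and values. How spots were scanned, flagged or background-corrected by the authors is not given in the sources used here, and the files hold no background, flag or print-block columns. The authors also deposited a table of 22656 clones with 1 linear ratio per array, after over before treatment. The median ratio per array lay between 0.924 and 1.07, and the log2 ratio correlated across clones with the normalized log2 ratio computed here at r between 0.899 and 0.996. The direction of the ratio was thus settled from the data, while the method that centred it was not given. The sources used here give no upper limit of the intensities, and 0 to 5 clones per array exceeded 65000.

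The intensities were corrected with limma's normexp method (offset 50) and normalized within each slide by loess (span 0.3), with limma 3.58.1 in R 4.3.3. The files gave no background measure, so the planned filter on probes above background was replaced by a filter on listing: a clone was tested if at least 3 of the 4 arrays of every condition listed it, which left 14582 clones. The 4 arrays of a condition were averaged as the mean of the 2 dye orientations, so that a dye effect cancels, and counted as 1 value, since they measure the same pair of RNA extracts. The 15 condition values therefore carried all tests. One limma model had an intercept and a linear slope on hours for each chemical, with 9 residual degrees of freedom, and slopes are given in log2 units per 24 h. A second, additive limma model had the time point as a factor and the chemical, with 8 residual degrees of freedom. It tested each time against before treatment, averaged over the 3 chemicals, and the level differences between chemicals. Calls have a Benjamini-Hochberg adjusted p below 0.05 over all clones tested. Single conditions have no replicate extract and no test, so clones at least 1 log2 unit from before treatment in the same direction on all 4 arrays were counted. For comparison, clones that passed this size on all 4 arrays but followed the dye were counted too. The p-values measure the spread of condition values around each model, which mixes biological, culture and array differences; a test against before treatment leaves out the spread of the before-treatment RNA. Each condition was 1 RNA extract, so no p-value covers the spread between repeated cultures of a condition. The number of conditions, and not that of arrays, sets the residual degrees of freedom.

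The labelled dyes were checked. The lowest intensities were higher in Cy3 than in Cy5 on 119 of 120 slides, and the clone-specific dye effect estimated from the other conditions had the labelled sign on 60 of 60 arrays. On simulated arrays of the same 14582 clones, each simulated size had 50 changed clones. The TSA slope test called 8% of clones with a slope of 0.5 log2 units per 24 h and 58% with 1. It called 92% with 2 and 100% with 3, and 2.27% of its calls were false. For the slope difference between TSA and DMSO the shares at these 4 sizes were 2%, 20%, 84% and 98%, with 3.77% false. For the level difference between HMBA and DMSO, 24% of clones changed by 0.5 and 90% of those changed by 1 log2 unit were called, with 5.99% false. At 6 h against before treatment these shares were 38% and 94%, with 8.29% false. The simulated noise was drawn separately for each clone, so it lacked the part that clones of 1 plate row share on the real arrays. The simulated shares, those of false calls included, therefore need not hold for the real arrays.

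Neither the files nor the reference gene table of assembly GRCm38.p6 pairs the clone identifiers with genes, and 0 of the 22656 identifiers matched that table. No gene is therefore named, and the 27 gene lists fixed before the data were examined could not be tested. The naming rule fixed at that time was written for named genes. After the data were seen it was narrowed to the 2 clones with the largest positive and the 2 with the largest negative mean slope over the 3 chemicals, among called clones whose 4 arrays had the same sign in the condition of their largest change.

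The alternatives were the signals without background correction, the array median in place of loess, arrays scaled to the same spread, weaker and stricter listing filters, the deposited ratios, time ranks, a fit of all 60 arrays with the condition as a random block, each dye orientation alone, and leaving out each technical replicate, time point and chemical. Contrasts between time points, the removal of plate, plate-row or plate-quadrant medians from each array, and settings that leave out HMBA at 1 h or turn the sign of its arrays were chosen after the data were seen. Leaving out a time point or chemical also leaves fewer residual degrees of freedom, so a lower count there need not mean that calls rest on it. The slides also limit 1 comparison. DMSO arrays carried all H3 clones on the first slide, while HMBA and TSA arrays carried H3 plates 121 to 159 on the second, so slide layout cannot be told apart from DMSO as a batch.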

Results

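Expression after treatment was measured relative to expression before treatment in mouse erythroleukemia cells, a virus-transformed red cell precursor line that matures in culture when given an inducer. DMSO, HMBA and TSA were each followed at 1, 6, 12, 24 and 36 h, with 4 technical arrays per condition. The arrays listed between 16550 and 21087 clones each, and 14582 clones were tested. Median intensity before treatment ranged from 299 to 1050 per array. The pair of arrays sharing a dye orientation correlated across clones with a median r of 0.482 for Cy5 and 0.515 for Cy3, while arrays of opposite orientation correlated at a median of 0.0907. The HMBA 1 h arrays in Cy3 correlated at r = -0.33, against the direction that arrays of 1 condition should share, so the direction at HMBA 1 h is not settled. Of the variance of the difference between these arrays, 66.2% lay between rows of the clone plates, the highest share among 30 pairs of the same RNA and dye orientation. For the HMBA 1 h arrays in Cy5 it was 53.4%. The cause was not tested, and 4 of 4 HMBA 1 h arrays had the labelled dye sign. At 1 h, arrays of opposite orientation correlated between -0.386 and -0.290 with DMSO, between -0.116 and -0.0816 with TSA and between -0.534 and 0.364 with HMBA, and these arrays lie behind the changes at 1 h. Clones are spotted cDNAs without gene names here, and several can represent the same gene.

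The first comparison asked when expression departed from its level before treatment, averaged over the 3 chemicals. After 1 h, 34 of the 14582 clones had changed, 16 of them higher and 18 lower. At 6 h the number was 1697, with 858 higher and 839 lower, and at 12 h it was 1977, with 954 higher and 1023 lower. It was 1197 at 24 h, with 649 higher and 548 lower, and 1044 at 36 h, with 520 higher and 524 lower. Called clones differed from before treatment by a median of 0.54 log2 units in size at 6 h, 0.53 at 12 h, 0.59 at 24 h and 0.57 at 36 h. The 16 clones that had risen by 1 h had a median of 0.85 at 1 h, 0.97 at 6 h and 0.37 at 36 h. The 18 that had fallen stood at a median of -0.81 at 1 h, -0.93 at 6 h and -0.46 at 36 h.

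**Figure D1:**
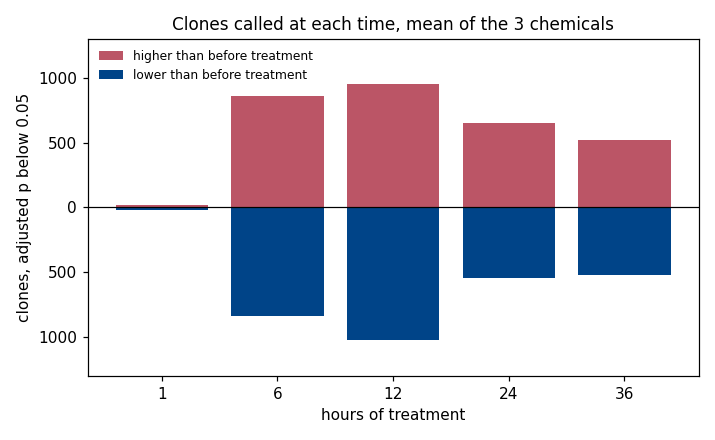
Number of clones called higher (upward bars) or lower (downward bars) than before treatment at each time in hours, for the mean of the 3 chemicals in the additive limma model. The counts go from 34 in all at 1 h to 1977 at 12 h and 1044 at 36 h.

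A direct contrast of 36 h with 6 h called 25 clones, 14 of them higher and 11 lower at 36 h. The 14 had a median of -0.52 log2 units at 6 h and 2.57 at 36 h, averaged over the 3 chemicals. Of the 14, 4 were called lower than before treatment at 6 h. With TSA alone their median at 6 h was 0.36, with 9 of the 14 above 0. The 11 had a median of 1.48 at 6 h and 0.23 at 36 h. A call in this contrast favours values far apart at 6 h and 36 h. Between 6 h and 1 h 72 clones differed, 43 higher and 29 lower at 6 h. Between 36 h and 12 h limma called 0 clones, with 1147 at an unadjusted p under 0.05. These contrasts were chosen after the data were seen. The 36 h and 6 h contrast had 65 calls with the deposited ratios, 29 of them higher and 36 lower, and 0 without replicate 1; the 6 h and 1 h contrast had 0 calls without 12 h, without DMSO, HMBA or TSA, without the HMBA 1 h condition and on the Cy3 arrays alone, and the 1 h count was 15 without the HMBA 1 h condition. Without HMBA the counts at 1, 6, 12, 24 and 36 h were 0, 283, 480, 505 and 133. Without DMSO they were 0, 634, 761, 232 and 211. These fits had fewer conditions and residual degrees of freedom, so the lower counts need not show a dependence on that chemical. Which direction held more clones at a time also turned with the setting.

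Single conditions were described by size alone. At 36 h, 58 clones were at least 1 log2 unit from before treatment on all 4 arrays with DMSO (23 higher and 35 lower), 71 with HMBA (50 higher and 21 lower) and 110 with TSA (88 higher and 22 lower). Clones that passed the same size but followed the dye numbered 0, 0 and 1 in these conditions. At 1 h the counts were 12 with DMSO, 8 with HMBA and 5 with TSA, against 29, 14 and 11 clones that followed the dye. With DMSO and TSA fewer clones thus passed than followed the dye. The dye count reflects dye effects and is no chance level, so it does not settle whether the large changes at 1 h are real. With HMBA even the order of the counts is not settled at 1 h. Without replicate 3, 120 clones passed and 22 followed the dye. With the sign of replicate 3 turned the numbers were 50 and 0, and with that of replicate 4 turned they were 0 and 50. At 6 h they were 68, 173 and 101, against 3, 13 and 1; in arrays scaled to the same spread they were 130, 80 and 116, so the order of the chemicals turned. With HMBA at 12 h, 89 clones passed and 60 followed the dye. The numbers were 29 and 23 with scaled arrays, 139 and 70 without replicate 1 and 156 and 93 without replicate 3. Without replicate 4 the order turned, with 116 passing and 198 following the dye. The order of HMBA and TSA at 36 h turned with the rule: clones whose mean over the arrays passed numbered 363 with HMBA and 287 with TSA, the Cy5 arrays alone gave 423 and 204, and without replicate 4 the counts were 148 and 125.

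The second comparison asked which clones had a linear slope on time over the 36 h, which does not require a steady course. Averaged over the 3 chemicals, 376 clones had a slope, 130 rising and 246 falling. The rising clones had a median of 0.34 log2 units at 36 h with DMSO, 0.79 with HMBA and 1.01 with TSA. At 1 h their medians were -0.07, -0.12 and -0.05, and that with HMBA was 0.06 with the sign of replicate 3 turned. The falling clones stood above before treatment at 1 h, with medians of 0.17, 0.38 and 0.40, and below it at 36 h, with medians of -0.16, -0.21 and -0.24. A call for a falling slope favours high early values. The HMBA median at 1 h was 0.26 and 0.38 with the sign of replicate 3 or 4 turned, and 0.25 in the 226 falling clones called without HMBA 1 h. The mean slope had 5 calls without 36 h, 8 without 6 h and 1 without TSA. The excess of falling clones turned into an excess of rising ones on the Cy5 arrays alone (28 rising and 12 falling), on the Cy3 arrays alone (81 and 23), without 24 h (55 and 20), without DMSO (53 and 12) and without HMBA (50 and 10).

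Clone H3126G09 rose with a mean slope of 2.51 log2 units per 24 h (SE 0.29, 95% interval 1.89 to 3.14, limma adjusted p = 0.0024). It stood at 1.52 ± 0.07 (SD, n = 4 technical arrays) after 36 h of DMSO, 2.76 ± 0.21 after HMBA and 4.66 ± 0.13 after TSA, the last a 25.3-fold increase. With HMBA it was at -1.27 ± 0.32 at 6 h and still at -0.29 ± 0.20 at 24 h. Clone H3126A10, from the same plate as H3126G09, had a mean slope of 2.46 (SE 0.28, limma adjusted p = 0.0024). It stood at 5.00 ± 0.57 after 36 h of TSA, 2.64 ± 0.29 after HMBA and 1.14 ± 0.35 after DMSO. Whether these 2 clones represent the same gene is not known here. Clone H3052G06 had the steepest mean decline, with a slope of -1.38 (SE 0.14, adjusted p = 0.00181), and stood at -0.94 ± 0.27 after 36 h of DMSO, -2.98 ± 0.36 after HMBA and -1.97 ± 0.10 after TSA. Clone H3144G06 had a mean slope of -1.29 (SE 0.16, adjusted p = 0.00316), made up of -1.29 with DMSO, -2.86 with HMBA and 0.27 with TSA. At 36 h it stood at -2.20 ± 0.56, -3.79 ± 0.41 and 0.35 ± 0.32 in that order. For H3126G09, H3126A10 and H3052G06 no slope difference between chemicals was called. Their lowest limma adjusted p-values were 0.451, 0.287 and 0.465, each for TSA minus DMSO. H3126G09, H3126A10 and H3144G06 come from the H3 plates that DMSO arrays carried on another slide than HMBA and TSA arrays. Their DMSO values are thus set beside values from another slide. Without TSA the mean slope was 1.97 for H3126G09 (adjusted p = 0.129), 1.79 for H3126A10 (0.139) and -1.32 for H3052G06 (0.081), and without HMBA it was -0.51 for H3144G06 (0.129). Slopes stayed close to those over all times without 6 h, at 2.47 and 2.42 for the rising clones (both 0.0546) and -1.24 for H3144G06 (0.0611), and were 2.15 for H3126G09 (0.0516) and 1.97 for H3126A10 (0.056) without 36 h.

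**Figure D2:**
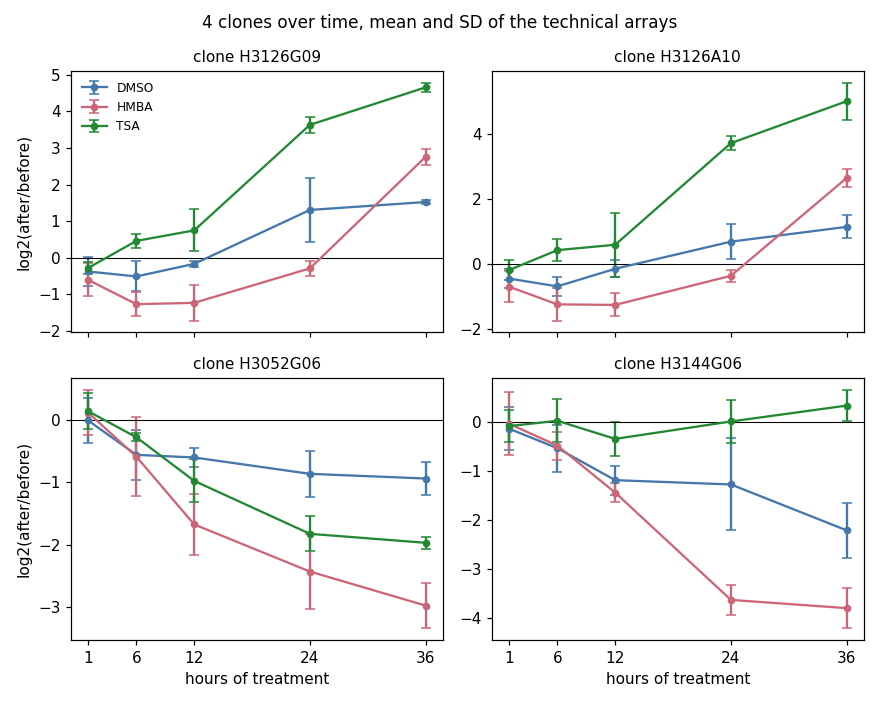
Log2 ratio of expression after over before treatment against hours of treatment for 4 clones, with 1 line per chemical; points are means and bars the SD of the technical arrays of a condition. H3126G09 and H3126A10 reach 4.66 and 5.00 after 36 h of TSA, and H3144G06 reaches -3.79 with HMBA and 0.35 with TSA.

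In the shared fit, the 3 chemicals gave different numbers of slope calls. TSA had 192, of which 119 rose and 73 fell. The rising clones had a median of 1.71 log2 units after 36 h of TSA, 0.31 after HMBA and 0.031 after DMSO. The falling clones were at 0.51 after 1 h of TSA and at -0.36 after 36 h. HMBA had 65 calls, 49 rising and 16 falling, with medians of 0.93 and -0.89 after 36 h of HMBA. A slope call in 1 chemical favours large late values in that chemical, so these medians do not test a difference between chemicals. For DMSO limma called 0 clones, with 579 of the 14582 at an unadjusted p under 0.05, fewer than chance alone gives. The median 95% half-width was 0.37 log2 units per 24 h for each chemical, since the fit used 1 spread estimate per clone for all 3. The log2 ratios had a median SD per array of 0.497 with DMSO, 0.694 with HMBA and 0.584 with TSA. In arrays scaled to the same spread there were 0 slope calls for DMSO, 5 for HMBA and 774 for TSA. The numbers of calls therefore do not rank the chemicals. At an unadjusted limma p under 0.05 HMBA had 2242 clones and TSA 2192, nearly equal numbers despite the 65 and 192 calls. The HMBA and TSA calls shared 3 rising clones, where independent lists would share 0.4, and 2 falling clones, where they would share 0.0801. With plate-row medians removed they shared 1 and 3, against 0.0806 and 0.0651. Both tests used the same spread estimate of a clone, so the lists are not independent. The overlap therefore need not show a shared response. Slopes correlated across clones at r = 0.36 between DMSO and HMBA, 0.17 between DMSO and TSA and 0.21 between HMBA and TSA, and at 0.34, 0.15 and 0.29 with plate-row medians removed; clones are not independent replicates. The HMBA count was 1 with the deposited ratios, and the TSA count was 0 without 36 h and 221 rising and 315 falling without replicate 4. Of the variance of slopes, 28.9% with DMSO, 27.5% with HMBA and 17.7% with TSA lay between rows of the clone plates; with plate-row medians removed, HMBA had 18 calls, 7 of them among the 65.

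**Figure D3:**
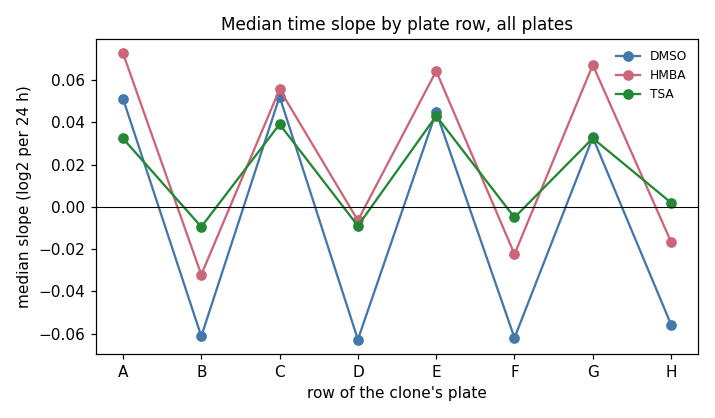
Median time slope of all tested clones, in log2 units per 24 h, against the row letter of the clone's plate, with 1 line per chemical. With DMSO the medians of rows A, C, E and G lie between 0.0328 and 0.0522, and those of rows B, D, F and H lie between -0.0628 and -0.0557.

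The difference in slope between chemicals was tested directly. TSA and DMSO differed for 5 clones, 5 of them steeper with TSA. Their TSA slopes lay between 1.12 and 2.79 log2 units per 24 h, their HMBA slopes between -0.24 and -0.0198 and their DMSO slopes between -0.73 and 0.22. After 36 h their median was 3.04 with TSA, 0.0079 with HMBA and -0.19 with DMSO. TSA and HMBA differed for 8 clones, 6 with a higher and 2 with a lower TSA slope. H3144G06 was among the 6, with a difference of 3.13 (SE 0.39, 95% interval 2.29 to 3.98, adjusted p = 0.00981). With plate-row medians removed its difference was 2.95 (SE 0.42, limma adjusted p = 0.0553), 1 clone was called and 0 of the 8 were called again. With plate medians removed it was 3.02 (SE 0.41, adjusted p = 0.0302), and 5 of the 8 were called again. With plate-quadrant medians removed it was 2.77 (SE 0.41, adjusted p = 0.0443), and 3 of the 8 were called again. HMBA and DMSO differed for 0 clones in limma, with 822 at an unadjusted p under 0.05; the median 95% half-width of a slope difference, unadjusted for the number of clones, was 0.53. Other splits of the same conditions gave as many slope differences often enough that these counts are not told from chance. Both fell to 0 without replicate 3, 6 h or 36 h, and the TSA and DMSO calls were 41 higher and 35 lower with TSA in arrays scaled to the same spread and 4 higher and 6 lower without replicate 4.

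The third comparison asked whether chemicals differed in level over the 5 matched times. TSA and HMBA differed for 661 clones, 167 higher and 494 lower with TSA, by a median of 0.61 log2 units in size. TSA and DMSO differed for 343 clones, 205 higher and 138 lower with TSA, by a median of 0.67. HMBA and DMSO differed for 138 clones, 116 higher and 22 lower with HMBA, by a median of 0.63. DMSO arrays had another slide layout than all others, so a batch of slides and DMSO cannot be told apart, while TSA and HMBA arrays shared a layout. In this order, the counts were 130, 15 and 0 without 6 h, 30, 0 and 0 without 12 h, 34, 5 and 13 without 24 h and 122, 23 and 0 without 36 h, where 7 of the 23 were higher and 16 lower with TSA. They were 921, 653 and 263 with plate-row and 1280, 859 and 526 with plate-quadrant medians removed, and arrays scaled to the same spread gave 380, 785 and 96.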

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

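The tests of the slide layout that HMBA and TSA share, of a slide batch for DMSO and of the normalization, and the splits that swap chemicals within times, were chosen after the results were seen, and so was the look at the wells touching the run described below; the test of position on the print plates was chosen after the pattern was seen but before its own value was.

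Slopes of clones from the same plate row moved together. Between plate rows lay 28.9% of the variance of DMSO slopes, against 0.0634% with shuffled rows. The position of clones on the print plates is a candidate explanation: in differences between 2 arrays of the same RNA and dye orientation, a median of 28.5% of the variance lay between plate rows over 30 pairs, against -0.0222% with shuffled rows. The normalization applied here is argued against as the source, since 28.6% of the variance of DMSO slopes lay between plate rows with no background correction and no loess. No biological explanation was tested.

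TSA and DMSO slopes differed for 5 clones, 3 of them in adjacent wells of 1 plate. The tables argue against a position effect of the layout shared with HMBA, since the highest HMBA slope of the 5 was -0.0198, and against a dye effect, since the lowest TSA slope in either orientation alone was 1.11. Carry-over between wells stays open: over all plates, TSA slopes of adjacent wells correlated by 0.0365 more than those of wells 2 to 11 columns apart, and a difference this small had been set beforehand as evidence against it. That bound did not suit this pattern, since it spreads 3 wells over all plates; the 5 tested wells touching them, looked at after the correlation was seen, had TSA slopes from -0.055 to 1.99 with a median of 0.12, against 2.24 to 2.79 in the 3 wells, and decide neither way. Chance cannot be excluded, as 12 of 100 splits of the 10 conditions gave at least 5 calls (highest other 28), as did 4 of the 16 that swap chemicals within times (highest other 7), and an effect of the chemical is also open.

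TSA and HMBA slopes differed for 8 clones, and chance cannot be excluded, as 19 of 100 splits gave as many (highest other 281), and so did 5 of the 16 that swap within times (highest other 86). For HMBA and DMSO slopes the real count of 0 makes the splits uninformative, as 100 of 100 give as many by construction; the highest gave 299, and the highest of those that swap within times gave 1. Splits with several times the real count point to a structure of the conditions, whose nature was not tested; the highest counts came from splits that break the matching of times. H3144G06 differed in slope between TSA and HMBA by 3.13, and by 2.95 with a limma adjusted p of 0.0553 with plate-row medians removed. The difference was 3.02 (adjusted p = 0.0302) with plate medians and 2.77 (0.0443) with plate-quadrant medians removed.

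Levels differed for 343 clones between TSA and DMSO, 138 between HMBA and DMSO and 661 between TSA and HMBA. Of 100 splits, 1, the real split, gave as many, and the highest of the others were 206, 0 and 89, but most of these splits break the matching of times. The 16 splits that swap chemicals within times are too few for a share under 0.05; the highest of the others among them were 0, 3 and 84. Clones printed on the other slide of the DMSO arrays were called 0.857 times as often as the rest in the differences from DMSO. This is below the ratio set beforehand for that move as the source. Between TSA and HMBA, which share a layout, they were called 1.84 times as often. Their share thus differs from the rest without a move too, and the ratio alone cannot isolate the move. A slide batch of all DMSO arrays cannot be told apart from the chemical, since 0 DMSO arrays had the layout of the others.

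Of 88 sets of 4 arrays tested for an array apart from the rest, 5 had one, where chance gives about 1 in 20. H3126A10 was at -0.021 on DMSO 1 h replicate 1 (others -0.62 to -0.54) and at 4.04 on TSA 24 h replicate 3 (others 3.58 to 3.63). H3144G06 was at -0.98 on HMBA 1 h replicate 4 (others 0.21 to 0.44). H3052G06 was at -1.54 on HMBA 24 h replicate 4 (others -2.79 to -2.69) and at -1.49 on TSA 12 h replicate 4 (others -0.85 to -0.73).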

How the results depend on the processing

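Counts at 6, 12, 24 and 36 h against before treatment stayed within 1.5 times of the main value with the deposited ratios, without background correction, with the array median, with scaled arrays and with plate medians removed. With the deposited ratios, 170 of the 192 TSA slope calls, 327 of the 376 mean slope calls and 1 of the 65 HMBA slope calls were called again in the same direction, and with plate-row medians removed these were 125, 195 and 7. The 4 named clones kept the direction of their mean slope in each alternative that tested them; H3126A10 and H3144G06 were left out when clones had to be listed on every array and without replicate 1. Scaling moved the TSA slope split from 119 higher and 73 lower to 317 and 457, the TSA minus DMSO slope split from 5 and 0 to 41 and 35, the TSA minus HMBA slope split from 6 and 2 to 16 and 12 and the HMBA slope split from 49 and 16 to 3 and 2. The array median moved the TSA slope split to 92 and 25 and that of 36 h against 6 h from 14 and 11 to 24 and 29. The larger direction of the mean slopes (130 higher and 246 lower) turned with time ranks (136 and 124), on either dye orientation alone (28 and 12, and 81 and 23), without replicate 3 (32 and 15) and without 6 h (6 and 2), 24 h (55 and 20), DMSO (53 and 12) or HMBA (50 and 10). That of the TSA slopes turned with scaling, in the fit of 60 arrays (343 and 488), without replicate 4 (221 and 315) and without 1 h (139 and 156). That of the HMBA slopes turned with plate-row (8 and 10) and plate-quadrant medians removed (2 and 6), without replicate 2 (1 and 2) or 3 (0 and 2), and to 0 and 1 with the deposited ratios, without background correction and without 36 h. The split of 36 h against 6 h turned with the deposited ratios (29 and 36), without background correction (31 and 39), with scaled arrays (27 and 31), on clones listed on every array (28 and 51), in the fit of 60 arrays (305 and 487), with plate, plate-row or plate-quadrant medians removed (28 and 37, 36 and 51, 51 and 84) and without HMBA 1 h (14 and 20) or replicate 4 (3 and 4), and that of 6 h against 1 h turned in the fit of 60 arrays (275 and 277) and on Cy5 arrays (3 and 4). The TSA minus HMBA slope split turned in the fit of 60 arrays (102 and 159) and without replicate 4 (82 and 152), which also turned that of the TSA minus DMSO slopes (4 and 6), and the TSA minus DMSO level split turned without 36 h (7 and 16). The splits against before treatment turned in several settings at each time, for example without TSA to 19 and 6 at 1 h, 564 and 477 at 12 h and 422 and 264 at 36 h, and on Cy5 arrays to 426 and 500 at 24 h; those of most size counts in single conditions turned in at least 1 setting, with DMSO at 36 h to 77 and 68 on Cy5 arrays. Size counts before 36 h moved too: over single replicates left out, 13 to 120 clones passed with HMBA at 1 h (8 with all) and 116 to 156 with HMBA at 12 h (89), the mean of the arrays gave 184 and 444, and scaling gave 0 and 29. With plate-row medians removed, 3 of the 5 TSA minus DMSO and 0 of the 8 TSA minus HMBA slope calls were called again. No paired analysis was possible because the 4 replicate numbers are arrays of the same pair of RNA extracts and are averaged before the fit. Local background subtraction, loess per print block, a choice among probes of a gene, a choice between files holding the same probes, a batch block and the gene lists were not run, since the files hold no background, block or gene columns, the files of an array hold different clones, and slide layout follows DMSO. Intensities have no background measure, so signal over background cannot limit the clones tested. The values given next are counts of calls that moved by more than 1.5 times; the cause was not tested, and those with plate medians, turned signs or HMBA 1 h left out were chosen after the data were seen. Slopes, levels and times name the tests; mean slopes average the 3 chemicals, times are against before treatment unless a second time is given, and large changes are size counts.

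Signals without background correction gave 1 for HMBA slopes and 70 for 36 h against 6 h. The array median in place of loess gave 39 for HMBA slopes, 117 for TSA slopes, 72 for HMBA minus DMSO levels and 53 for 36 h against 6 h. Scaling arrays to the same spread gave 5 for HMBA slopes, 774 for TSA slopes, 76 for TSA minus DMSO slopes, 28 for TSA minus HMBA slopes, 785 for TSA minus DMSO levels and 380 for TSA minus HMBA levels. Calls also numbered 58 for 36 h against 6 h and 88 for large changes with DMSO at 36 h. Restricted to clones listed on every array, the counts were 17 for HMBA slopes, 94 for TSA slopes, 0 for TSA minus DMSO slopes, 0 for TSA minus HMBA slopes, 250 for HMBA minus DMSO levels and 79 for 36 h against 6 h. The same setting gave 66 for large changes with TSA at 36 h. The deposited ratios gave 1 for HMBA slopes and 65 for 36 h against 6 h. Time ranks gave 234 for HMBA slopes, 98 for TSA slopes, 0 for TSA minus DMSO slopes and 1 for TSA minus HMBA slopes. The fit of 60 arrays, whose condition correlation of 0.03 leaves technical arrays nearly independent, gave 61 for DMSO slopes, 956 for HMBA slopes, 831 for TSA slopes, 1224 for mean slopes, 185 for TSA minus DMSO slopes and 22 for HMBA minus DMSO slopes. Under it there were 261 for TSA minus HMBA slopes, 508 for 1 h, 2903 for 6 h, 3135 for 12 h, 2146 for 24 h and 1789 for 36 h. Calls further numbered 1436 for TSA minus DMSO levels, 1146 for HMBA minus DMSO levels, 2028 for TSA minus HMBA levels, 792 for 36 h against 6 h, 552 for 6 h against 1 h and 397 for 36 h against 12 h. Arrays with the treated RNA in Cy5 alone gave 11 for HMBA slopes, 42 for TSA slopes, 40 for mean slopes, 1 for TSA minus DMSO slopes, 3 for TSA minus HMBA slopes and 788 for 1 h. It also gave 903 for HMBA minus DMSO levels, 386 for TSA minus HMBA levels, 0 for 36 h against 6 h, 7 for 6 h against 1 h, 145 for large changes with DMSO at 36 h and 423 for large changes with HMBA at 36 h. There were also 204 for large changes with TSA at 36 h. Arrays with the treated RNA in Cy3 alone gave 305 for HMBA slopes, 104 for mean slopes, 1 for TSA minus DMSO slopes, 119 for TSA minus HMBA slopes, 19 for 1 h and 1129 for 12 h. Calls also numbered 698 for TSA minus DMSO levels, 236 for HMBA minus DMSO levels, 194 for TSA minus HMBA levels, 0 for 36 h against 6 h, 0 for 6 h against 1 h and 120 for large changes with DMSO at 36 h. The same setting gave 224 for large changes with HMBA at 36 h and 282 for large changes with TSA at 36 h. Without replicate 1 there were 133 for HMBA slopes, 119 for TSA slopes, 186 for mean slopes, 16 for TSA minus HMBA slopes, 1161 for 12 h and 621 for 36 h. Under it there were 207 for TSA minus DMSO levels, 72 for HMBA minus DMSO levels, 355 for TSA minus HMBA levels, 0 for 36 h against 6 h and 30 for 6 h against 1 h. Without replicate 2 there were 3 for HMBA slopes, 84 for TSA slopes, 135 for mean slopes, 51 for HMBA minus DMSO levels, 428 for TSA minus HMBA levels and 43 for 36 h against 6 h. Calls further numbered 44 for 6 h against 1 h. Without replicate 3 there were 2 for HMBA slopes, 52 for TSA slopes, 47 for mean slopes, 0 for TSA minus DMSO slopes, 0 for TSA minus HMBA slopes and 21 for 1 h. It also gave 1038 for 6 h, 571 for 36 h, 113 for TSA minus DMSO levels, 54 for HMBA minus DMSO levels, 342 for TSA minus HMBA levels and 16 for 36 h against 6 h. There were also 14 for 6 h against 1 h and 107 for large changes with HMBA at 36 h. Without replicate 4 there were 846 for HMBA slopes, 536 for TSA slopes, 10 for TSA minus DMSO slopes, 1 for HMBA minus DMSO slopes, 234 for TSA minus HMBA slopes and 1025 for 6 h. Calls also numbered 1119 for 12 h, 693 for 36 h, 221 for TSA minus DMSO levels, 34 for HMBA minus DMSO levels, 7 for 36 h against 6 h and 29 for 6 h against 1 h. The same setting gave 148 for large changes with HMBA at 36 h. A size rule on the mean of the arrays gave 133 for large changes with DMSO at 36 h, 363 for large changes with HMBA at 36 h and 287 for large changes with TSA at 36 h. Without 1 h there were 295 for TSA slopes, 1 for TSA minus DMSO slopes, 631 for TSA minus DMSO levels and 48 for 36 h against 6 h. Without 6 h there were 0 for HMBA slopes, 13 for TSA slopes, 8 for mean slopes, 0 for TSA minus DMSO slopes, 0 for TSA minus HMBA slopes and 15 for TSA minus DMSO levels. Under it there were 0 for HMBA minus DMSO levels and 130 for TSA minus HMBA levels. Without 12 h there were 5 for HMBA slopes, 76 for TSA slopes, 157 for mean slopes, 1 for TSA minus DMSO slopes, 2 for TSA minus HMBA slopes and 0 for TSA minus DMSO levels. Calls further numbered 0 for HMBA minus DMSO levels, 30 for TSA minus HMBA levels, 0 for 36 h against 6 h and 0 for 6 h against 1 h. Without 24 h there were 75 for mean slopes, 0 for TSA minus DMSO slopes, 14 for TSA minus HMBA slopes, 5 for TSA minus DMSO levels, 13 for HMBA minus DMSO levels and 34 for TSA minus HMBA levels. It also gave 34 for 6 h against 1 h. Without 36 h there were 1 for DMSO slopes, 1 for HMBA slopes, 0 for TSA slopes, 5 for mean slopes, 0 for TSA minus DMSO slopes and 0 for TSA minus HMBA slopes. There were also 23 for TSA minus DMSO levels, 0 for HMBA minus DMSO levels and 122 for TSA minus HMBA levels. Without DMSO there were 65 for mean slopes, 0 for 1 h, 634 for 6 h, 761 for 12 h, 232 for 24 h and 211 for 36 h. Calls also numbered 1 for 36 h against 6 h and 0 for 6 h against 1 h. Without HMBA there were 60 for mean slopes, 0 for 1 h, 283 for 6 h, 480 for 12 h, 505 for 24 h and 133 for 36 h. The same setting gave 0 for 36 h against 6 h and 0 for 6 h against 1 h. Without TSA there were 1 for mean slopes, 936 for 6 h, 1041 for 12 h, 686 for 36 h, 0 for 36 h against 6 h and 0 for 6 h against 1 h. Without the HMBA 1 h condition there were 9 for TSA minus DMSO slopes, 15 for 1 h, 237 for HMBA minus DMSO levels and 0 for 6 h against 1 h. Turning the sign of HMBA 1 h array 3 gave 4 for HMBA slopes, 77 for TSA slopes, 157 for mean slopes, 17 for 1 h, 134 for TSA minus DMSO levels and 0 for 36 h against 6 h. Under it there were 27 for 6 h against 1 h. Turning the sign of HMBA 1 h array 4 gave 110 for HMBA slopes, 2 for 1 h and 61 for HMBA minus DMSO levels. Removing the median of each plate gave 26 for HMBA slopes, 8 for TSA minus DMSO slopes and 65 for 36 h against 6 h. Removing the median of each plate row gave 1 for DMSO slopes, 18 for HMBA slopes, 11 for TSA minus DMSO slopes, 1 for TSA minus HMBA slopes, 57 for 1 h and 653 for TSA minus DMSO levels. Calls further numbered 263 for HMBA minus DMSO levels, 87 for 36 h against 6 h, 138 for 6 h against 1 h and 45 for large changes with HMBA at 36 h. Removing the median of each plate quadrant gave 8 for HMBA slopes, 292 for TSA slopes, 62 for 1 h, 859 for TSA minus DMSO levels, 526 for HMBA minus DMSO levels and 1280 for TSA minus HMBA levels. It also gave 135 for 36 h against 6 h and 191 for 6 h against 1 h.

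Where leaving out a technical replicate, time point or chemical moved a count by more than 1.5 times, counts over all such settings ranged from 0 to 1 for DMSO slopes, 0 to 846 for HMBA slopes, 0 to 536 for TSA slopes, 1 to 493 for mean slopes, 0 to 10 for TSA minus DMSO slopes and 0 to 1 for HMBA minus DMSO slopes. These ranges were also 0 to 234 for TSA minus HMBA slopes, 0 to 32 for 1 h, 283 to 1648 for 6 h, 480 to 1929 for 12 h, 232 to 1250 for 24 h and 133 to 1095 for 36 h. They further were 0 to 631 for TSA minus DMSO levels, 0 to 151 for HMBA minus DMSO levels, 30 to 856 for TSA minus HMBA levels, 0 to 48 for 36 h against 6 h, 0 to 51 for 6 h against 1 h and 93 to 148 for large changes with HMBA at 36 h.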

Other observations

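The contrast of 36 h with 6 h was chosen after the data were seen. The 14 clones higher at 36 h than at 6 h had a median of -1.49 log2 units after 6 h of HMBA, -0.48 after 6 h of DMSO and 0.36 after 6 h of TSA. At 36 h their medians were 2.30, 1.37 and 3.87. The 11 clones that fell over this interval had medians of 1.92, 1.36 and 1.18 at 6 h with HMBA, DMSO and TSA, and of 0.57, 0.27 and -0.020 at 36 h. The differences between chemicals were not tested.

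Of the clones called at some time against before treatment, 1610 were called at 1 time, 737 at 2, 420 at 3, 385 at 4 and 13 at 5, and 1 clone was called in opposite directions at different times. Among the 870 pairs of arrays of the same orientation, 1 correlated below -0.3, the HMBA 1 h pair. Of the HMBA 1 h arrays, 4 of 4 had the labelled dye sign and 2 were among the 4 arrays with the highest spread of log2 ratios, up to an SD of 1.02.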
